A study of Xenopus laevis with 6 samples.

How the data were processed

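RNA from 3 pools of untreated and 3 pools of bhh-treated stage 24 pronephric explants of Xenopus laevis was measured on 1-colour Affymetrix arrays, 1 array per pool. Per the labels' protocols, 300 explants were extracted per sample, and 1 µg of total RNA was amplified into biotin-labelled cRNA. The deposited values are intensity values on a linear scale, 1 signal per probe set and array, made by the authors with MAS5, per the submitters' processing notes; its version and further settings are not given in the sources used here. MAS5 subtracts mismatch probes and scales each array to a common level, so dim signals are noisy and the scaling assumes that most genes do not change. The 2% trimmed mean of the 6 columns differed by a ratio of 1.00004 at most, so the intensities were used as deposited. No pair of arrays held more than 0.245% identical values, and all 6 were kept as separate samples.

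The table held 15611 probe sets, of which 120 Affymetrix controls were left out of the tests. Of the remaining 15491, the platform's gene table gave 1 gene symbol for 9304, several for 195 and none for 5992. Symbols were updated through gene identifiers to the RefSeq table of assembly Xenopus_laevis_v10.1, used here for names only: 9227 matched, 77 did not and kept the older name. Probe sets with several symbols were not named. No detection calls were used here. As a background, the 95th percentile of 44 bacterial and tag control probe sets was taken (signal 37.6). Where a group's mean lay below it, the ratio is given as "at least", from means of log2 signals in which each array of the dim group under 37.6 was set to 37.6; other folds are ratios of geometric means.

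Log2 signals were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend, two-sided), after removal of the lowest 25% of probe sets by mean log2 signal, which left 11618, and p-values were adjusted with the Benjamini-Hochberg method at a threshold of 0.05. Of these, 7463 carried 1 gene symbol, for 6202 distinct symbols. For gene lists, the brightest probe set of each symbol was used, and 24 of 25 lists with at least 5 measured members were tested with camera at its preset correlation, adjusted over the 24 lists. camera with an estimated correlation and fry were run beside it; of the 13 lists that passed, the somite and skeletal muscle list alone kept its call with an estimated correlation. Exact two-sided permutation tests of the mean of member z-scores per array cannot go below 0.1 with 3 against 3 arrays. Lists, tests and the rule for naming genes were fixed before the data were examined. That rule took all measured members of the hedgehog lists, the 12 probe sets with the smallest p in each direction among those with 1 symbol, separated groups and a brighter group at or above the median signal of all probe sets (160.6), and up to 4 members with the smallest p in every other list.

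Group labels carry replicate numbers 1 to 3, and the data were checked for pairing by these numbers. The deviations of arrays from their group means correlated between same-numbered arrays at 0.407, 0.178 and 0.298 for numbers 1, 2 and 3. Each was over the 0.1 taken as the limit for pairing, and pairing by number was allowed for in a blocked fit beside the main one. Mainly the arrays numbered 1 stood apart: untreated 2 with treated 3 gave 0.173 and untreated 3 with treated 2 gave 0.147. Both are also over 0.1, so numbers 2 and 3 were hardly told apart. Deviations cancel within a group, so arrays numbered 1 that stand apart together also raise the values among the others. The check thus does not show that numbers 2 and 3 pair the samples. The labels do not say what a number stands for. Hybridization control probe sets gave a like order: their median signal was 2235, 1233 and 879 on untreated arrays 1, 2 and 3 and 1795, 1393 and 780 on treated arrays 1, 2 and 3. The GAPDH 3' to 5' signal ratio was 4.10, 3.59 and 3.31 on untreated and 4.42, 3.67 and 3.01 on treated arrays, and the actin ratio was 0.191, 0.344 and 0.342 on untreated and 0.158, 0.605 and 0.665 on treated arrays. The design without a block was fixed as the main one, and the blocked value is printed where it differs in its call or moves a list's count of calls by more than 1.5 times. In simulated data for this comparison over 11618 probe sets, the fit without a block recovered 54% of 100 probe sets changed by 1 on the log2 scale and 89% of 100 changed by 2, with 2.7% false calls among its calls. The blocked fit recovered 44% and 79%, with 0.81% false calls, in another simulated set with a spread shared by same-numbered arrays. The rates of the fits thus come from different data and do not rank them. In a simulation of 20 lists, the 1 shifted list passed and none of the others did. Its probe sets were drawn independently of each other, so it does not cover false list calls that come from correlation between genes.

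Alternatives were quantile normalization, scaling to a common trimmed mean or median, an offset of 15.7 signal units before the logarithm, no filter and a filter of 50%, a variance without trend, array weights, the replicate block, each array left out in turn, an ordinary equal-variance test per probe set, a minimum of 1.5-fold, a threshold of 0.1, other set tests, other ways to join probe sets of a gene, and lists without genes that another list holds. Leaving out both arrays numbered 1, the block with quantile normalization, probe sets shared by homeologs and the hedgehog components without ihh were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.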

Results

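RNA was profiled from pronephric explants of Xenopus laevis, small blocks of flank tissue that contain the rudiment of the larval kidney, cut from embryos at stage 24. The explants were either untreated or treated with bhh (banded hedgehog, a secreted signalling protein of the hedgehog family whose gene is now named ihh). The labels do not say how bhh was supplied. Each group held 3 pools, and 300 explants of about 70 × 100 × 70 µm were extracted for a pool. Each pool was hybridised to its own Affymetrix X. laevis array, so the 6 arrays gave 15611 probe set intensities each, of which 11618 were tested. All 6 arrays had a trimmed mean signal of 500.1, and their medians lay between 149.9 and 170.6. With 3 arrays per group, the number of arrays limits the precision of every value below. X. laevis carries pairs of genes from an ancient genome duplication, marked .L and .S, which are given separately.

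The comparison of treated with untreated explants asks which genes differ with bhh treatment in the tissue that forms the pronephros. The labels name no mock-treated group, so a response to bhh cannot be told apart from effects of the treatment procedure. The gene for the ligand, ihh.S, had a signal of 22.7 ± 11.7 (SD, n = 3) in untreated explants, below the 95th percentile of bacterial and tag control probe sets (37.6), and of 2967 ± 149 (SD, n = 3) in treated explants. It was at least 78.9-fold higher (adjusted p = 6.9e-07). Among the genes named below, those known to respond to hedgehog rose in part, as did some lateral plate mesoderm genes, while several genes of the kidney rudiment and of muscle fell. Of the 11618 probe sets, 86 rose and 74 fell at an adjusted p under 0.05, and 88 of these 160 changed by more than 2-fold, 45 upward and 43 downward. With the replicate number as a block, 733 probe sets passed, 424 higher and 309 lower, and all 160 were among them. The 3 arrays of one group lay wholly above or below those of the other for 2127 probe sets, or 18.3% of those tested. Chance gives 10% if all splits into 3 and 3 arrays are equally likely, which leaves out any pairing by replicate number. The unblocked count depended on single arrays: it was 60 without untreated array 2, 74 without untreated array 3, 71 without treated array 2 and 69 without treated array 3.

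Among the hedgehog response genes, 5 of 15 measured members rose. These were hhip.L, which encodes a membrane protein that binds hedgehog ligands, the forkhead transcription factor genes foxf1.L and foxd1.L, and the growth genes mycn.S and ccnd1.L. The signal of hhip.L went from 150 ± 35.4 to 641 ± 203 (SD, n = 3 each), a log2 fold change of 2.07 ± 0.25 (SE, adjusted p = 0.0024), and its second probe set rose by 1.39 ± 0.21. The log2 fold changes of foxf1.L and foxd1.L were 1.44 ± 0.18 and 1.47 ± 0.19 (adjusted p = 0.0030 for both). A dimmer second probe set of foxd1.L had 0.85 ± 0.27 and did not pass (adjusted p = 0.211). mycn.S rose from 454 ± 74.0 to 976 ± 111, or 2.16-fold, and ccnd1.L rose 1.66-fold. One member fell: myf5.L, a gene that starts the muscle programme, by 1.34 on the log2 scale (SE 0.24, adjusted p = 0.020). The remaining 9 did not pass the test, among them foxc2.S, with a log2 fold change of 1.58 ± 0.67, which passed with the replicate block (adjusted p = 3.6e-04), with array weights (0.0083) and without treated array 1 (0.0071), and mycn.L, with 0.47 ± 0.13 (blocked adjusted p = 0.011). Adjusted over the list alone, 6 members were higher and 1 lower. The list as a whole was shifted upward, with a median log2 fold change of 0.40 (camera adjusted p = 7.8e-07). Its exact permutation p over arrays was 0.1, the smallest that 3 against 3 arrays allow, and the adjusted p = 0.074 with an estimated correlation. The call of ccnd1.L was lost when any 1 of the 6 arrays was left out (adjusted p up to 0.144), and that of myf5.L without untreated array 2, untreated array 3 or treated array 3 (up to 0.104).

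The 9 measured hedgehog components, genes for ligands, receptors and transducers of the pathway, held 2 that rose, ihh.S and hhip.L; 7 did not pass. As bhh is the product of ihh and its way of supply is not given, the ihh.S signal does not tell introduced RNA from the embryo's own. Adjusted over the list alone the same number, 2, were higher. The receptor component smo.L had a log2 fold change of 0.65 ± 0.29 (adjusted p = 0.391, or 0.031 with the replicate block), and its dimmer probe set 0.32 ± 0.26 (0.486 with the block). Smaller values were found for the transcription factor genes gli3.L (0.33 ± 0.20), gli2.L (0.24 ± 0.29) and gli2.S (0.18 ± 0.28), for boc.L (0.27 ± 0.29), shh.L (-0.05 ± 0.24) and the kinase gene prkaca.S (-0.30 ± 0.26). The list was shifted upward (camera adjusted p = 6.1e-04), also without ihh (median log2 fold change 0.26, adjusted p = 0.040), a setting chosen after seeing the data. Apart from ihh.S, hhip.L was the only member that passed the limma test. With an estimated correlation the list's adjusted p = 0.074. The probe sets of gli1.S and ptch1.S, genes that hedgehog signalling is known to induce, were too dim to be tested. gli1.S had a signal of 4.33 ± 0.86 in untreated and 22.0 ± 2.93 in treated explants, and ptch1.S 15.2 ± 2.32 and 24.9 ± 7.54 (SD, n = 3 each), so both groups lay under the control level of 37.6 and no fold is given.

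**Figure D1:**
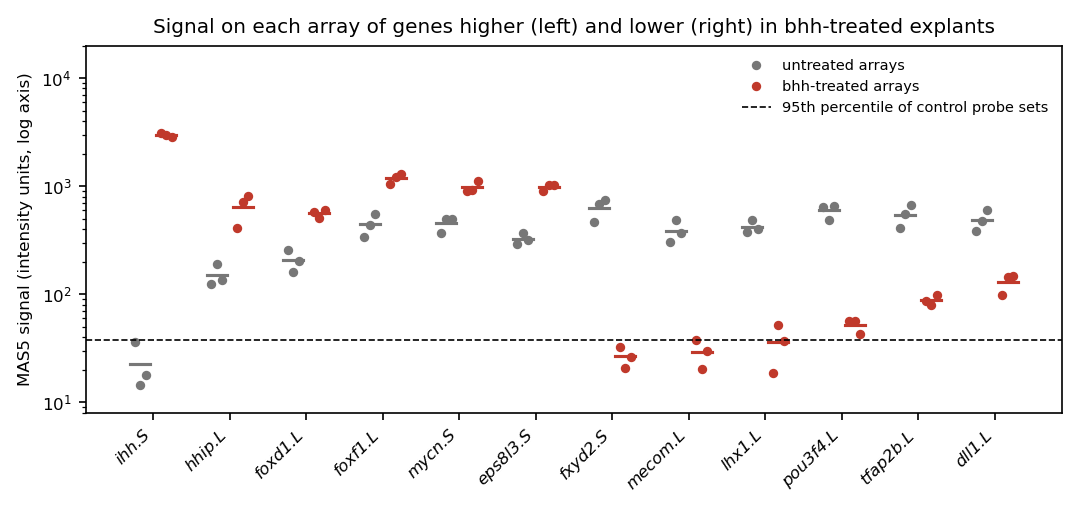
Signal of each array (log axis, MAS5 intensity units) for 12 genes, with untreated arrays in grey, bhh-treated arrays in red, short lines for the group means and a dashed line at 37.6, the 95th percentile of the bacterial and tag control probe sets. The treated arrays lie above all untreated arrays for the genes from ihh.S to eps8l3.S and below all of them from fxyd2.S to dll1.L, and the dim groups of ihh.S, fxyd2.S, mecom.L and lhx1.L have means under the dashed line.

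Genes of the kidney rudiment were among the largest decreases. The signal of fxyd2.S, which encodes a small subunit of the sodium pump, was 627 ± 145 (SD, n = 3) in untreated and 26.5 ± 5.95 in treated explants, at least 16.3-fold lower (adjusted p = 6.0e-06). The transcription factor gene mecom.L was at least 10.1-fold lower (387 ± 89.99 to 29.1 ± 8.57, adjusted p = 5.4e-05), and lhx1.L, a homeobox gene needed for kidney formation, at least 10.02-fold lower (421 ± 59.4 to 35.7 ± 16.3, adjusted p = 3.1e-04), with 1 of its 3 treated arrays above the control level. dll1.L, which encodes a Notch ligand, fell by 1.91 on the log2 scale (SE 0.22, adjusted p = 0.0015). Among the 36 measured pronephric patterning factors, these last 3 fell and 2 rose, foxf1.L and osr1.L, the latter from 143 ± 21.0 to 282 ± 33.0 (adjusted p = 0.025); 31 did not pass. The osr1.L call was lost without untreated array 2 or 3 or treated array 2 or 3, where only foxf1.L rose. Not counted, as the listed name pcdh8 did not match it, was pcdh8.2.L, which rose (log2 fold change 1.04 ± 0.13, adjusted p = 0.0024). Adjusted over the list alone, 4 of the measured members were higher and 4 lower, and 5 and 5 with the replicate block. pax8.L (log2 fold change -0.33 ± 0.27) and wt1.L (-0.61 ± 0.35), both dim, and gata3.S (0.14 ± 0.29) did not pass. The 3 probe sets of pax2.L disagreed in size: 1 fell, by 1.58 on the log2 scale (adjusted p = 0.035), while the brightest had -0.55 ± 0.33 and the other -1.10 ± 0.28 (adjusted p = 0.114, or 0.049 with the block). The list was shifted downward (median -0.16, camera adjusted p = 0.038), but the adjusted p = 0.158 with an estimated correlation and 0.054 with the replicate block. Leaving out 1 array also ended this list's call for untreated array 1, 2 or 3 or treated array 1 (adjusted p up to 0.129). In all it was lost in 10 of 23 settings, with the largest adjusted p, 0.992, when the dimmer 50% of probe sets were left out.

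Of 22 measured pronephric tubule and duct transporters, fxyd2.S fell and slc7a8.S, an amino acid transporter gene, rose by a log2 fold change of 0.68 ± 0.14 (adjusted p = 0.039); 20 did not pass, and 2 were higher and 1 lower adjusted over the list alone. slc7a7.L had a log2 fold change of 0.64 ± 0.15 (adjusted p = 0.080, or 0.012 with the replicate block) and rgn.L of -0.73 ± 0.23. As a list they were not shifted (camera adjusted p = 0.896). The call of slc7a8.S was lost when any 1 array was left out (adjusted p up to 0.180). Only 4 markers of the glomus, the filtering part of the pronephros, were measured, too few for a list test, and none passed the limma test (1, foxc2.S, at an unadjusted p under 0.05); the values of foxc2.S are given above, and the log2 fold changes of wt1.L, cask.S and efnb2.S were -0.61, -0.18 and -0.15.

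Muscle genes were shifted downward as a list. Of 45 measured somite and skeletal muscle genes, 33 had a log2 fold change below 0, 7 fell and none rose in the limma test (20 lower and 2 higher at an unadjusted p under 0.05). The 7 became 2 without untreated array 2, 3 without untreated array 3, and 10, with 1 higher, without treated array 1. Not counted, as the listed name des did not match them, were des.1.S, which fell (-0.90 ± 0.16, adjusted p = 0.018), and des.1.L (-0.16 ± 0.15). Adjusted over the list alone 19 were lower and 2 higher, and with the replicate block 20 and 3. The myosin heavy chain gene myh8.L fell from 5931 ± 96.5 to 3316 ± 40.4 at its brightest probe set (log2 fold change -0.84 ± 0.12, adjusted p = 0.0043) and by 1.18 at another, while the dimmest had -0.50 ± 0.12 (adjusted p = 0.080, or 0.0073 with the replicate block). The creatine kinase gene ckb.L, which is on the list but is named for the brain-type enzyme, fell 2.09-fold, from 10364 ± 902 to 4961 ± 357 (adjusted p = 0.0027). The gene of the muscle-type enzyme, ckm.L, had -0.74 ± 0.16 at its brightest probe set (adjusted p = 0.053, or 1.6e-04 with the replicate block). Its other probe sets had -0.73 ± 0.15 (adjusted p = 0.039) and -0.34 ± 0.12 (adjusted p = 0.270). eno3.L, the muscle form of the glycolytic enzyme enolase, fell 3.06-fold, and pax3.S, a transcription factor gene of muscle and neural crest precursors, fell by 1.70 on the log2 scale (SE 0.25, adjusted p = 0.0070). Its partner pax3.L had the opposite sign, 0.77 ± 0.19 (adjusted p = 0.093, or 0.0037 with the replicate block), as had myod1.S, a myogenic regulator (0.79 ± 0.17, adjusted p = 0.053, or 0.0059 with the block). The list had a median log2 fold change of -0.36 (camera adjusted p = 3.5e-09), and it kept its call with an estimated correlation (adjusted p = 0.046). The pax3.S call was lost without untreated array 2 or 3 (adjusted p up to 0.068) and that of eno3.L without untreated array 2 (0.082).

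**Figure D2:**
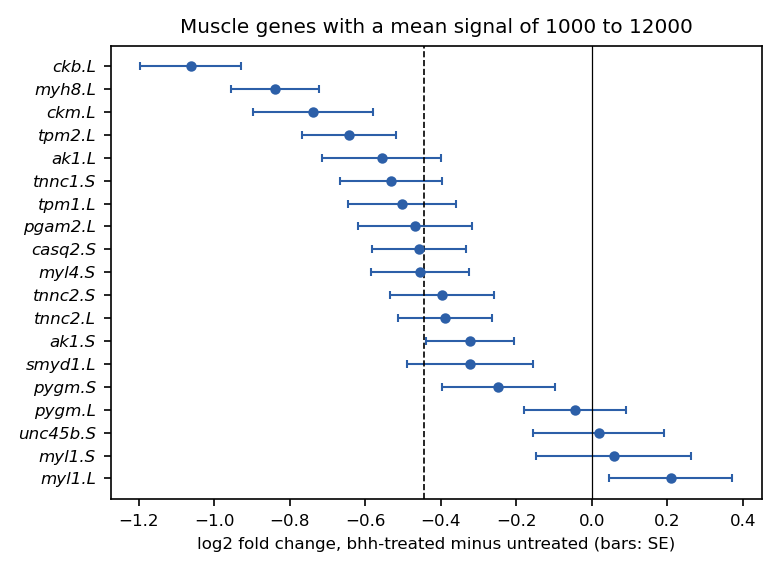
Log2 fold change (treated minus untreated, with SE bars, 3 arrays per group) of the 19 muscle list members with a mean signal between 1000 and 12000; the solid line marks 0 and the dashed line the weighted mean of -0.45. Values run from -1.06 for ckb.L to 0.21 for myl1.L.

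Glycolysis and hypoxia genes shifted downward as a list as well: 30 of 40 were below 0, with a median of -0.20 (camera adjusted p = 6.1e-04; adjusted p = 0.163 with an estimated correlation). Of these, 3 fell, namely eno3.L, the aldolase gene aldoc.L (1.91-fold, adjusted p = 0.0094) and the triosephosphate isomerase gene tpi1.S (1.61-fold, adjusted p = 0.015). The other 37 did not pass, and 1 was higher and 4 lower adjusted over the list alone (1 and 9 with the replicate block). Of 4 probe sets of tpi1.S, 3 fell and the dimmest had -0.35 ± 0.22 (adjusted p = 0.575). The aldoc.L call was lost without untreated array 3 (adjusted p = 0.053) and that of tpi1.S without untreated array 2 or 3 or treated array 2 or 3 (up to 0.111). In the list of stress, wounding and apoptosis genes none of 40 passed the limma test (2 higher and 5 lower at an unadjusted p under 0.05), and 1 was higher and 2 lower adjusted over the list alone, and 2 and 4 with the replicate block. Its median was -0.21 (camera adjusted p = 0.0079; adjusted p = 0.138 with an estimated correlation), with values such as -0.96 ± 0.25 for hmox1.S and 0.54 ± 0.13 for ddit4.S, which passed with the block (adjusted p = 0.011 and 0.0083).

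Some genes of the lateral plate, smooth muscle and heart rose. Of 29 measured members, 3 rose: foxf1.L, the GATA factor gene gata5.S (110 ± 15.3 to 277 ± 18.7, 2.54-fold, adjusted p = 0.0038) and hand1.L, a lateral plate transcription factor gene (1060 ± 138 to 2111 ± 189, log2 fold change 1.00 ± 0.14, adjusted p = 0.0043). The other 26 did not pass, and 8 were higher and 1 lower adjusted over the list alone (9 and 1 with the replicate block). The median was 0.24 (camera adjusted p = 0.0020; adjusted p = 0.074 with an estimated correlation, and 0.873 once genes that another list also holds were removed). The gut endoderm list, which shares gata5 with it, had 1 riser among 16 and 5 higher against 1 lower adjusted over the list alone (4 and 1 with the block). Its median was 0.20 (camera adjusted p = 0.044), but the adjusted p = 0.338 with an estimated correlation and 0.071 with the replicate block, and the call was lost without untreated array 2 or 3 or treated array 1 or 2 (up to 0.194), in all in 11 of 23 settings. gata6.L had a log2 fold change of 0.56 ± 0.14 (adjusted p = 0.114, or 0.012 with the block).

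Targets of BMP and Wnt signalling also leaned upward. Among 16 BMP targets the homeobox gene ventx2.1.S rose 1.99-fold (adjusted p = 0.0498) and 15 did not pass, with 5 higher and 0 lower adjusted over the list alone and 4 and 0 with the replicate block. The BMP median was 0.36 (camera adjusted p = 3.6e-04; adjusted p = 0.074 with an estimated correlation). Their next members were id3 (0.64 ± 0.15, adjusted p = 0.086) and msx1.L (0.82 ± 0.20, adjusted p = 0.096), which passed with the replicate block (0.0033 and 0.0018); a second probe set of id3 did not (0.70 ± 0.29, blocked adjusted p = 0.10). Of 14 Wnt targets 2 rose, ccnd1.L and wif1.S, which encodes a secreted Wnt inhibitor (148 ± 15.7 to 305 ± 18.0, adjusted p = 0.012), and 12 did not pass, with 4 higher and 1 lower both adjusted over the list alone and with the block. The median was 0.43 (camera adjusted p = 6.4e-05; adjusted p = 0.074 with an estimated correlation). The ventx2.1.S call was lost without any array but treated array 1 (adjusted p up to 0.287), and that of wif1.S without untreated array 2 or 3 or treated array 2 or 3 (up to 0.074).

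Of 9 members of the Notch target list, dll1.L fell and 8 did not pass. The counts were 0 higher and 2 lower both adjusted over the list alone and with the replicate block. Since dll1.L encodes a Notch ligand, as does jag1.L of the list, the list does not read Notch targets alone. The target gene hey1.S had a log2 fold change of -0.54 ± 0.17 at its brightest probe set (limma adjusted p = 0.216, or 0.039 with the block). Its dimmer probe sets passed in neither fit. The Notch list shifted downward (median -0.17, camera adjusted p = 0.020), not with an estimated correlation (adjusted p = 0.345) and not without untreated array 2 or treated array 1 (up to 0.097), in all lost in 4 of 22 settings. The 11 trunk and posterior Hox genes were shifted upward as a list (median 0.28, camera adjusted p = 0.038) without a single member past the limma test, over all or adjusted over the list alone. There, 3 were higher at an unadjusted p under 0.05, and 1 with the replicate block. The adjusted p = 0.338 with an estimated correlation and 0.059 with the replicate block, and the call was also lost without untreated array 2 or 3 or treated array 1 (up to 0.260), in all in 10 of 22 settings. Among 116 cell cycle genes 3 rose, ccnd1.L, cks2.L (1.49-fold) and wee1.S (1.54-fold), and 113 did not pass; 3 were higher adjusted over the list alone and 10 with the replicate block. The median shift was 0.07 (camera adjusted p = 0.038; adjusted p = 0.338 with an estimated correlation), lost without untreated array 1 or treated array 1 or 2 (up to 0.198) and in 12 of 23 settings in all. The calls of cks2.L and wee1.S were lost without any 1 array (up to 0.235 and 0.273).

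Of 41 neural tube and neural crest genes, 3 fell and 1 rose. tfap2b.L, an AP-2 transcription factor gene, fell from 540 ± 129 to 87.6 ± 9.25 (log2 fold change -2.60 ± 0.21, adjusted p = 1.1e-04), and pax3.S and prph.S fell 3.25-fold and 2.03-fold. snai1.S rose 1.71-fold. Over the list alone 4 were higher and 6 lower, as with the replicate block, and the list was not shifted (camera adjusted p = 0.149). The prph.S and snai1.S calls were each lost when 1 of 4 arrays was left out, untreated array 2 or 3 and treated array 2 for both, treated array 1 for prph.S (adjusted p up to 0.179) and treated array 3 for snai1.S (up to 0.109).

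Markers of other tissues that such a block could hold gave little in the camera tests. Neither the 22 blood genes (camera adjusted p = 0.389), the 11 endothelial genes (0.715), the 31 epidermal genes (0.238), the 29 genes of multiciliated cells and ionocytes (0.112), the 10 notochord genes (0.208) nor the 6 sclerotome and cartilage genes (0.084, or 0.0046 with the replicate block) were shifted as lists. With fry, by contrast, epidermis (fry adjusted p = 0.022) and notochord (0.014) were shifted upward and multiciliated cells and ionocytes downward (0.0060). Single genes that fell were the endothelial fli1.S (2.33-fold, adjusted p = 0.016) and the ciliary dynein gene dnali1.S (2.06-fold, adjusted p = 0.016). Adjusted over the list alone, the counts of higher and lower members were 0 and 2 for blood, 1 and 1 for endothelium, 0 and 1 for multiciliated cells and ionocytes, 2 and 0 for sclerotome and cartilage, and 0 and 0 for epidermis and notochord. With the replicate block they were 1 and 2 for blood, 2 and 1 for endothelium, 1 and 2 for multiciliated cells and ionocytes, 3 and 0 for sclerotome and cartilage, and 1 and 0 for both epidermis and notochord. In the sclerotome list sox9.S and pdgfra.L had log2 fold changes of 1.09 ± 0.29 and 0.85 ± 0.27, past the threshold with the block (6.3e-05 and 0.0012), which a dimmer probe set of pdgfra.L was not (0.59 ± 0.20, blocked adjusted p = 0.086). The calls of fli1.S and dnali1.S were lost without untreated array 2 or treated array 2, that of fli1.S also without treated array 3 and that of dnali1.S without untreated array 3 (adjusted p up to 0.101 for both).

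Of 13 retinoic acid targets, both copies of tgm2, a transglutaminase gene, fell, tgm2.S by 2.41-fold (750 ± 40.5 to 312 ± 38.3, adjusted p = 0.0014) and tgm2.L by 2.07-fold (adjusted p = 0.0030), and the other 11 did not pass. In this list 1 was higher and 2 lower adjusted over the list alone. This list's median (0.10) and mean (-0.07) differ in sign, and it was not shifted (camera adjusted p = 0.819). The 34 extracellular matrix genes held 2 that rose, emilin1.L (2.28-fold, adjusted p = 0.0054) and vcan.L (1.73-fold, adjusted p = 0.028), and 1 that fell, col3a1.S (2.30-fold, adjusted p = 0.039), with 2 higher and 2 lower adjusted over the list alone, 6 and 4 with the replicate block, and no shift (camera adjusted p = 0.819). Its median (-0.01) and mean (0.0023) also differ in sign. None of the 12 FGF and MAPK targets passed the limma test over all probe sets, 1 was higher and 2 lower both at an unadjusted p under 0.05 and adjusted over the list alone, and the list was not shifted (camera adjusted p = 0.389). With the block cyp26a1.L was higher (adjusted p = 0.014) and egr1.L and dkk1.S were lower (0.011 and 0.023). The vcan.L and col3a1.S calls were lost without any 1 of 5 arrays (adjusted p up to 0.190 and 0.186), all but treated array 1 and all but treated array 3.

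**Figure D3:**
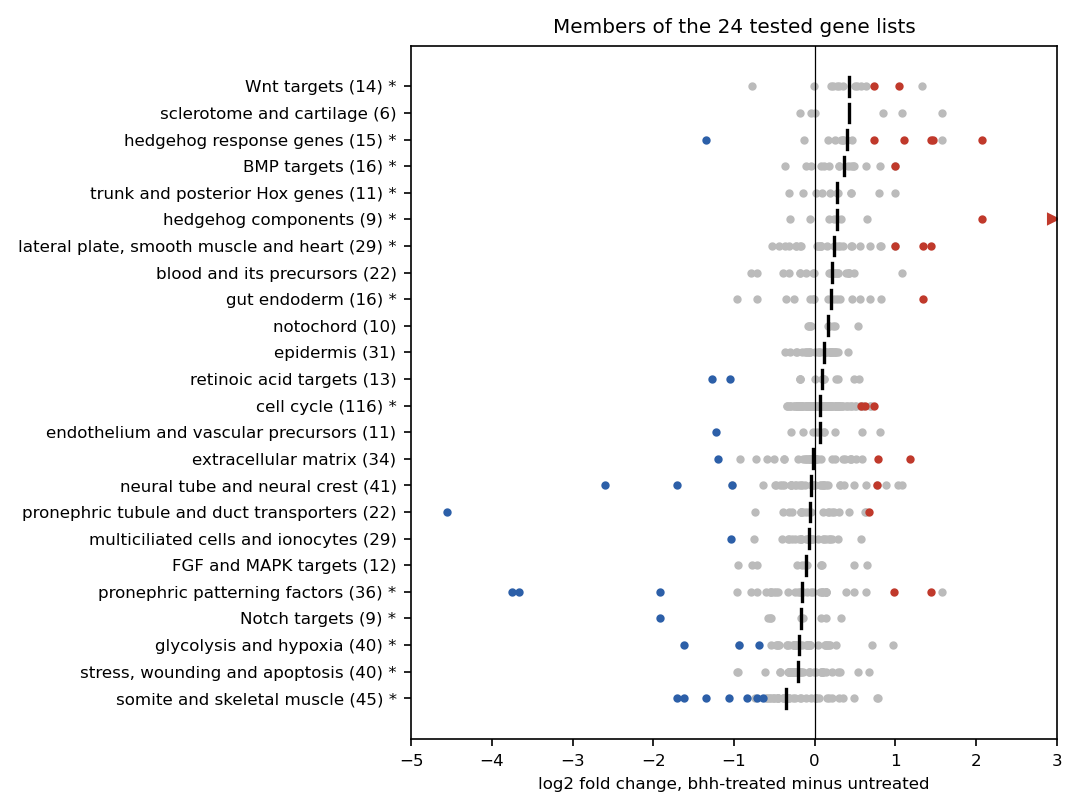
Log2 fold change (treated minus untreated) of each measured member of the 24 tested lists, with the number of members in brackets, black bars at list medians, red and blue points for members that rose or fell and grey points for the rest. An asterisk marks the 13 lists past the camera threshold, 8 higher and 5 lower; ihh.S lies beyond the right edge and is drawn as an arrowhead.

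Outside these lists, the rule for naming genes gave further strong changes. Higher in treated explants were eps8l3.S (325 ± 40.0 to 987 ± 72.4, 3.05-fold, adjusted p = 3.1e-04), cyyr1.L (2.60-fold, adjusted p = 3.7e-04), phyhdlb.L (2.31-fold), the adhesion genes nectin2.L (2.18-fold) and pcdh8.2.L (2.05-fold), the Wnt ligand gene wnt8a.L (129 ± 2.71 to 304 ± 2.32, 2.36-fold), the homeobox gene pitx3.L (3.02-fold) and the steroid hydroxylase gene cyp17a1.L (2.37-fold), all with an adjusted p of 0.0036 or less. A dimmer second probe set of cyp17a1.L had a log2 fold change of 0.35 ± 0.25 and did not pass (adjusted p = 0.641). Lower were the POU domain gene pou3f4.L, which fell from 595 ± 95.5 to 51.6 ± 8.09 (11.5-fold, adjusted p = 8.3e-06) at 1 probe set and by 1.83 on the log2 scale at the other, fst.L, which encodes the activin antagonist follistatin (2.41-fold, adjusted p = 0.0019), and the calcium-binding protein genes ocm4.3.L and ocm4.5.S (2.43-fold and 2.45-fold, adjusted p = 4.1e-04 and 0.0014). Nothing in the labels says that the pools came from separate clutches, so the p-values measure the spread between these samples, which may be technical.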

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

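The search among untested probe sets was chosen after the data had been seen. Of 3993 probe sets outside the tests, in the dimmest 25% or among the controls, 30 lay below the control level of 37.6 on every untreated array and above it on every treated array, and 25 lay the opposite way. In the limma fit without a filter on dim probe sets 4 of the 30 passed and 0 of the 25 (19 of them at an unadjusted p under 0.05). These signals appeared in data that the comparisons above do not use. The untreated signals of the 4 lie under the control level, where no fold is measured, so their adjusted p-values rest in part on unmeasured signal. tmem184b.L went from 14.4 ± 3.98 to 59.1 ± 13.5 (SD, n = 3 each; adjusted p = 0.0499) and rdd1.L from 13.9 ± 4.69 to 61.4 ± 5.64 (adjusted p = 0.032). The other 2 probe sets, which have no symbol here, went from 3.97 ± 1.12 to 42.4 ± 3.78 (adjusted p = 0.013) and from 23.3 ± 6.01 to 77.9 ± 10.5 (adjusted p = 0.043).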

How the results depend on the processing

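No gene past the threshold changed sign under any setting it was tested in. Among lists past the threshold in at least 1 of the settings compared, a median changed sign in 2 cases. Gut endoderm went from 0.20 to -0.012 without the genes that another list holds and lost its call. Sclerotome and cartilage, not past the threshold in the main fit, went from 0.43 to -0.014 without both arrays numbered 1. In that setting, chosen after seeing the data, its camera test passed (adjusted p = 0.028). Among its 6 measured members 3 were then higher and 0 lower in limma. The values below cover settings planned before the data were examined unless said otherwise. The count of 160 probe sets (86 higher, 74 lower) stayed within 1.5 times, from 134 to 164, under the 3 scalings, the offset, both filters and the minimum fold. It rose to 733 (424 and 309) with the replicate block, 657 (368 and 289) with array weights, and, with settings chosen after seeing the data, 591 (342 and 249) without both arrays numbered 1 and 687 (377 and 310) with the block and quantile normalization; each of these 4 kept all 160. The weights of the arrays numbered 1 were 0.416 and 0.390, and those of the others 1.02 to 3.03. The count was 95 (49 and 46) with a variance that has no trend, 5 (2 and 3) with an ordinary equal-variance test per probe set, which borrows no spread between probe sets, and 242 (137 higher) at a threshold of 0.1. Leaving out 1 array gave 60 to 187 probe sets, 33 to 115 higher and 25 to 72 lower; of the 160, 60 passed again without untreated array 2, 70 without untreated array 3, 71 without treated array 2 and 69 without treated array 3, with fewer samples in each. Of 47 named probe sets that passed, 30 passed in each setting in which they were tested (16 or 17 settings, the ordinary test not among these); the 17 others lost the call without at least 1 array, as given above.

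The number of lists higher fell from 8 to 5 with the dimmer 50% left out, to 4 without shared genes and to 0 with an estimated correlation; the number lower fell from 5 to 3 without shared genes and to 1 with an estimated correlation, and was 3 to 5 with 1 array left out. The cause of these drops was not tested. The hedgehog response list lost its call with an estimated correlation, a setting that cannot move its median (camera adjusted p = 0.074, range over its settings 3.1e-10 to 0.074). Its median of 0.398 became 0.921 with the dimmer 50% left out. Without both arrays numbered 1, a setting chosen after seeing the data, it was 0.639. fry passed 8 lists higher and 5 lower, of which epidermis, notochord and multiciliated cells and ionocytes did not pass camera, while Notch targets, Hox genes and cell cycle passed camera and not fry. Apart from the calls given above, the block changed no call of a list; it ended none of the named genes' calls and added 33. Of 2439 values of genes and lists under alternatives, 28 had the opposite sign of a value that was not past the threshold in either setting. Genes near the control level, gli1 and ptch1 among them, have no measurable fold on these arrays.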

Other observations

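The tests on somite tissue as the whole cause, on the 4 brighter kidney rudiment genes, on blood and on the introduced RNA below were chosen after the results were seen, as were the genes of this and the next paragraph. A family of small calcium-binding proteins, the ocm4 genes, fell together: all 8 tested probe sets, from 5 genes, were lower, with log2 fold changes from -1.29 to -0.79 and each past the threshold. Several of the 8 belong to ocm4.4.S alone, and probe sets of such a family may share probes or read each other's transcripts. They are thus not independent measurements. The ocm4 signals in untreated explants were high, for instance 6590 ± 721 for ocm4.1.L against 2942 ± 703 in treated explants (SD, n = 3 each). aldh1a1.L, which encodes a retinaldehyde dehydrogenase, fell by 1.77 on the log2 scale (SE 0.26, adjusted p = 0.0065), whereas its partner aldh1a1.S had -0.15 ± 0.32.

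Gene copies from the genome duplication mostly had the same sign where one was called. Of 812 pairs with both copies tested, 18 held at least 1 called copy, and in 16 of these both copies had the same sign, against 65.6% of all 812. The 2 exceptions were pax3 (L 0.77 ± 0.19, S -1.70 ± 0.25) and rbpms2 (L -1.44 ± 0.23, adjusted p = 0.013; S 0.04 ± 0.13). The forkhead gene foxc2.S varied widely between pools: its signal was 123, 254 and 409 on untreated arrays 1, 2 and 3 and 183, 1298 and 1435 on treated arrays 1, 2 and 3.

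No split of the arrays can settle whether the counts arise by chance, since 3 against 3 arrays make 10 splits and 3 pairs make 4 exchanges of labels. The real grouping gave 160 probe sets, and the highest of the other 9 splits gave 2; for lists the numbers were 13 and 2. The real grouping was thus the 1 of 10 splits with the highest count. With the block, the real labels gave 733 and the highest other exchange of labels within pairs gave 0, so 1 of 4 reached the real count. Among the splits that part all 3 pairs, the other 3 gave 0 probe sets each at an adjusted p under 0.05 in limma; those that part 1 pair gave 0 to 2.

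The muscle list was lower in treated explants. The highest median of the list under quantile or median scaling, which kept 153 and 147 of the 160 called probe sets, was -0.34. The choice among these scalings thus does not account for the shift. Their effect was small, with medians over all tested probe sets of -0.0027 and -0.0198, so a change of sign was hardly possible. Less somite tissue as the whole cause would lower abundant muscle transcripts by one factor, and 19 members with a signal between 1000 and 12000 gave a Cochran's Q of 81.3, then 32.7 in a second form made after the first was seen, which adds the variance between probe sets of one gene, where the threshold is 28.9. Neither is taken to exclude it, since probe sets of one gene also differ (myh8.L from -1.18 to -0.50) and that variance comes from 10 probe sets of 4 genes, some of which may share probes. A response to bhh, the explanation the design names, or to the treatment procedure thus cannot be told apart from less somite tissue. This holds for less tissue as all or part of the cause, as 9 myogenic regulators had a median of 0.012 ± 0.37 (SE). Among them myf5.L and pax3.S were lower and myod1.S and pax3.L above 0.

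The kidney rudiment genes lhx1.L, mecom.L and fxyd2.S were lower by at least 10-fold. All 3 kept the call under quantile and median scaling, with adjusted p no larger than 1.0e-04 in limma. These scalings gave a median log2 fold change over all tested probe sets of -0.0027 and -0.0198, against 0.0027 as deposited. Falls this large could thus hardly have lost their call, and the choice among these scalings does not account for them. If the treated explants had simply held less kidney rudiment, its other genes could have fallen as far, but pax8.L, pax2.L, osr1.L, wt1.L, gata3.S and hnf4a.S had a median of -0.44 ± 0.35 (SE), above the -1 set beforehand. The 4 of them with at least 1 log2 unit of room above the control level had -0.20 ± 0.53. This set cannot decide whether less rudiment tissue was the whole cause. Of its genes, osr1.L rose, and gata3 and hnf4a also stand in lists of other tissues. For pax2.L only the brightest probe set was used. Its other probe sets had log2 fold changes of -1.1 and -1.58, with treated means under the control level. A loss of tissue, as all or part of the cause, stays open. So does a response to bhh, the explanation named by the design, or to the treatment procedure.

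Among the tested probe sets, one that has no symbol here showed the largest rise after that of ihh.S: from 25.2 ± 10.3, under the control level, to 772 ± 120 (SD, n = 3 each), at least 20.4-fold (adjusted p = 1.3e-05). It shares its cluster number on the array with probe sets of hbg1.L, a globin gene, and of tuba5.S and ctsv.L, so more blood in the treated explants might raise it. The globin probe sets were looked at first, but 5 of 8, hbg1.L among them, had a group mean under the control level, so all 22 blood genes tested were used: their median log2 fold change was 0.22 ± 0.11 (SE), from -0.79 to 1.09 (hba3.L), and the brightest globin, hba-l5.L, had 0.30 ± 0.19, far below this rise. A candidate explanation is that it reads sequence of the introduced bhh RNA, such as untranslated globin sequence that expression vectors for Xenopus often carry. Over the 3 treated arrays the ratio of its signal to that of ihh.S had a coefficient of variation of 10.6%, which this explanation allows but would also hold for a gene that responds to bhh, and it stays open, as the sources used here give neither the probe sequences nor the way bhh was supplied.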
